A study of Mus musculus with 9 samples.

How the data were processed

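Total RNA of 9 samples, 3 samples of c-kit-positive cardiac stem cells (eCSCs), 3 samples of YFP-positive cardiomyocytes and 3 samples of normal adult cardiomyocytes, was labelled as biotin cRNA and hybridised to Illumina mouse bead arrays, per the labels. Groups and replicate numbers were taken from the sample titles. The titles call the YFP-positive samples in vitro, while the design text describes sorting from the heart, and this was not settled. The isoproterenol text stands in the protocol of every sample; it was read as describing the YFP-positive group, as the design text does, and whether the adult cells came from treated mice is not settled.

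The probe table gave 1 intensity per probe and array, deposited by the authors without normalization or background subtraction, as lowest signals of 75.0 to 91.7 and medians of 93.6 to 117.9 show. Between 33.85% and 42.07% of probes were detected per array. Per the file headers the column beside each signal is a detection p-value, but its values rise with the signal, so that it is a fraction: the share of negative control bead types dimmer than the probe. All of these values were whole shares of 936 control beads (tolerance 0.01), and 1 minus the value was used as the detection p. The authors also deposited a gene-level table of intensities, a normalized gene-level table and a series matrix on a log2-like scale; the submitters' processing notes name lumi 2.10.0 and R 2.15.3, and the transformation and normalization methods are not given in the sources used here. Each series matrix column followed the signals of the same sample (9 of 9), with direction and scale as log2 but flattened near background, and column medians from 6.655 to 6.672. At gene level, 5 normalized columns carried the number of another replicate of the same group, so that these values were used only at group level. A further 9 columns of the files that were matched to no sample were not used. No slide or chip position was given in the file headers.

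Signals were background corrected by normexp with the detection p-values, given an offset of 16, quantile normalized and taken to log2 (neqc in limma 3.58.1, R 4.3.3, and version 1.17.8 of data.table). Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3. Of 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 had none in the annotation used here. Symbols were updated from the RefSeq gene table of the mouse assembly GRCm38.p6, through the Entrez ID for 34807 probes and through the accession for 11, and 67 kept the given symbol. Using only probes with exactly 1 symbol is a detail that the fixed design did not state. Probes with a detection p under 0.05 on all 3 arrays of at least 1 group were kept (18180), and the brightest detected probe over the 9 arrays stood for a gene, which left 10024 genes; 19053 genes had a probe. Of the genes tested, 3836 had more than 1 detected probe, and probes of the same gene were called in opposite directions for 163 of these between YFP-positive cells and eCSCs, 218 between adult cells and eCSCs and 59 between the cardiomyocytes. Tnnt2, Mki67, Ptprc, Ly6a and Wt1 were not analysed here.

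All 9 arrays entered 1 linear model with a mean per group (lmFit and eBayes), and 3 differences and an F test were taken from it, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Shifts of 21 gene lists fixed before the data were examined were tested by camera with a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and fry as alternatives. The lists were sarcomere, calcium handling and ion channels, fetal and stress genes, fatty acid oxidation and muscle energy transfer, oxidative phosphorylation, glycolysis, cardiac transcription factors, stem and progenitor genes, cell cycle, atrial chamber, interferon response, and immediate early and heat shock genes, together with markers of fibroblasts, endothelium, leukocytes, mast cells, smooth muscle and pericytes, erythroid cells, epicardium, adipocytes and skeletal muscle. A further 4 lists (imprinted growth network, amino acid response, neutrophil granule and acute phase, hypertrophic stress) were chosen after the results were seen. The position of an array was its projection on the line from the eCSC mean to the adult mean. Gene overlap was set beside 100 simulations of unchanged groups that shared the eCSC arrays.

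Named genes followed a rule fixed before the data were examined: for each comparison the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, detected on all 3 arrays of the higher group, leaving out clone, predicted and locus names; up to 4 members of each list with the smallest adjusted p; and 17 genes named in advance, of which Kit, Myh6, Myh7, Nppa, Nppb, Actc1, Tnni3, Gata4, Nkx2-5, Ryr2, Atp2a2, Pecam1 and Col1a1 could be tested. In the comparison of 3 groups the 5 with the largest difference from both others were named. Names outside the rule are marked where they appear, and not every gene that met the rule is named.

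The steps after normalization and filtering were tested on simulated data over 10024 genes with known changes. Background correction, normalization, the detection filter and the choice of probes were not part of that test. In each simulation 100 genes changed 2-fold and 100 changed 4-fold, far fewer than were called in the real data. The shares of calls on unchanged genes given next need therefore not hold for the real comparisons. A 2-fold change was called in the true direction for 90% of 100 genes in the comparison of YFP-positive cells with eCSCs, 86% of adult cells with eCSCs and 89% of YFP-positive with adult cells, and a 4-fold change for 100% in each; of the calls 3.55%, 5.1% and 7.8% fell on unchanged genes. Alternatives were median scaling, no normalization, no background correction, the deposited gene-level tables and series matrix, other filters on dim probes, the mean of a gene's probes, each array left out in turn, the replicate number as a block, the 2 groups alone, a variance trend with robust estimation, array weights, a 2-fold minimum and other position measures. Median scaling on probes detected on all 9 arrays, and wider name matching of the gene-level tables, were added after the data were seen.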

Results

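Transcript levels were measured on 9 Illumina mouse bead arrays, 3 for each of 3 groups of heart-derived cells. The first group, called eCSCs here, held, per the labels, cardiac stem cells positive for the receptor c-kit and negative for the leukocyte antigen CD45, harvested at passage 4; no Kit probe was detected on these 3 arrays. The second held YFP-positive cardiomyocytes, sorted by fluorescence from the apex of the left ventricle 28 days after isoproterenol, a beta-adrenergic agonist that injures heart muscle, given at 200 mg per kg. In those mice a lentivirus carried Cre recombinase under c-kit control, so that Cre switched on a YFP reporter. The titles of these 3 samples say in vitro, whereas the design text describes sorting from the heart; the labels do not settle this. The third group held normal adult cardiomyocytes of the same reporter strain. The stated purpose was to test the identity of the new cardiomyocytes and how far they had differentiated.

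The arrays detected between 15326 and 19048 of 45281 probes each, and their median raw signals ran from 93.6 to 117.9. Across the genes tested, arrays of the same group correlated at r = 0.981 to 0.992 for eCSCs, 0.975 to 0.987 for YFP-positive and 0.982 to 0.987 for adult cardiomyocytes. Between YFP-positive and adult cardiomyocytes r was 0.875 to 0.923, and between YFP-positive cells and eCSCs 0.646 to 0.682; genes are not independent replicates. YFP-positive replicate 2 stood apart from replicates 1 and 3: its mean r with the adult arrays was 0.922 against 0.876 and 0.880, it detected 16802 probes against 19048 and 19002, and its array weight of 0.443 was the lowest of all 9. The number of arrays, 3 per group, limits the precision of every value. The labels do not say whether the 3 samples of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. All adjusted p-values for genes are Benjamini-Hochberg values of limma's moderated test over 10024 genes, and levels are normalized log2 signals. A gene undetected on every array of a group has only a bound there, given as at least N-fold: the brighter group's mean against the lowest signal of a detected probe on each dim array, or the dim probe's own signal where that was higher. A group in which a gene was detected on only some arrays is named with their number, and sizes against such a group are uncertain. Log2 sizes of dim genes also depend on the background correction, as shown for each comparison below.

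YFP-positive cardiomyocytes were first set against the eCSCs. They carried high levels of transcripts of the heart's contractile apparatus, many of which were not detected on any eCSC array. Myl3, a ventricular myosin light chain, stood at 14.80 ± 0.077 (SD, n = 3) and was at least 1070-fold higher than in eCSCs (adjusted p = 2.45e-15). Myl2 was at least 896-fold, the alpha myosin heavy chain Myh6 at least 839-fold, cardiac actin Actc1 at least 797-fold and Csrp3 at least 596-fold higher. Troponin I, Tnni3, was at least 76.7-fold higher (adjusted p = 3.53e-13), and the slow myosin Myh7 at least 5.54-fold (adjusted p = 7.8e-07). Of 22 sarcomere genes tested, 19 rose and 1 fell, with a median log2 difference of 7.66, or 7.44 with undetected members at their bound; adjusted over the list alone the counts were also 19 and 1. The list's shift had an adjusted p of 9.72e-13 by camera, and adjusted p = 0.0402 with an estimated correlation. The member that fell was Tpm1 (-1.52 ± 0.22 SE), read by the brightest of its detected probes and named after its values were seen. Its other detected probe fell as well, from 9.946 in eCSCs to 8.216 in YFP-positive and 6.433 in adult cells. Another Tpm1 probe was undetected on every array. Which forms of the transcript these probes read was not tested, here or in the comparisons below.

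Genes of calcium handling rose with them: 18 of 20 were called, 19 adjusted over the list alone, with a median of 3.18 (3.09 with bounds). Among them were the calcium release channel Ryr2, at least 115-fold higher (adjusted p = 1.53e-13), Hrc, at least 341-fold, Casq2, at least 120-fold, and the calcium pump Atp2a2, which eCSCs also expressed and which was 107-fold higher (6.74 ± 0.19 SE, adjusted p = 4.83e-13), a size that can be understated because its level of 14.81 in YFP-positive cells stood near the top of the arrays' range. The list's adjusted p was 3.27e-09, and adjusted p = 0.0578 with an estimated correlation. The fetal and stress list rose in 10 of 11 members, with a median of 4.86 (adjusted p = 9.45e-07; adjusted p = 0.0279 with an estimated correlation), led by the atrial natriuretic peptide Nppa, at least 674-fold higher (adjusted p = 4.77e-14); Nppb was 29.1-fold higher (4.86 ± 0.26 SE). Of 14 cardiac transcription factors, 13 rose and 1 fell, with a median of 2.64, or 2.49 with bounds (adjusted p = 8.8e-06; adjusted p = 0.0279 with an estimated correlation). The factor that fell was Isl1 (-1.81; detected on 1 of 3 YFP-positive arrays), named after its values were seen. Nkx2-5, detected on 2 of 3 eCSC arrays, was 10.5-fold higher (3.39 ± 0.17 SE), Hopx at least 94.1-fold and Gata4 at least 1.9-fold. The Gata4 call was lost in the deposited non-normalized gene-level table (adjusted p = 0.077). Counts adjusted over the list alone were the same as over all genes tested for these lists and for those below, unless another is given.

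Muscle energy genes rose too. Of 26 genes of fatty acid oxidation and energy transfer, 24 rose with a median of 3.16, or 3.15 with bounds (adjusted p = 1.11e-11; adjusted p = 0.107 with an estimated correlation). Lipoprotein lipase, Lpl, was at least 946-fold and the fatty acid binding protein Fabp3 at least 734-fold higher. Oxidative phosphorylation genes rose in 30 of 33 cases and fell in 1, with a median of 1.47 (adjusted p = 1.86e-08; adjusted p = 0.158 with an estimated correlation), and Cox8b, a muscle form of a respiratory chain subunit, was at least 451-fold higher. Glycolysis genes rose in 9 of 16 cases and fell in 2, with a median of 1.35 (adjusted p = 0.0167; adjusted p = 0.22 with an estimated correlation). All 32 cell cycle genes tested fell, with a median of -1.97 (adjusted p = 4.32e-09; adjusted p = 0.134 with an estimated correlation), Aurka among them (-4.14 ± 0.21 SE). Among genes detected on all 9 arrays the glycolysis list was not called (adjusted p = 0.0551).

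Markers of other cell types were also higher in YFP-positive cardiomyocytes than in the cultured eCSCs. Endothelial markers rose in 16 of 17 cases, with a median of 5.41, or 5.07 with bounds (adjusted p = 1.53e-08; adjusted p = 0.107 with an estimated correlation). Pecam1 was higher by at least 42.7-fold (adjusted p = 5.31e-12). Fibroblast and matrix markers rose in 17 of 24 and fell in 4, with a median of 1.48, or 1.35 with bounds (adjusted p = 0.000932; adjusted p = 0.215 with an estimated correlation). Dcn, detected on 1 of 3 eCSC arrays, was higher by 7.86 ± 0.24 SE and Col1a1 by 1.75 ± 0.27 SE on the log2 scale. Leukocyte markers rose in 16 of 18 and fell in 1, with a median of 3.06, or 2.75 with bounds (adjusted p = 8.19e-06; adjusted p = 0.175 with an estimated correlation). Mast cell markers rose in 7 of 8, with a median of 2.6, or 2.1 with bounds (adjusted p = 0.000628; adjusted p = 0.175 with an estimated correlation). Cpa3 was higher by at least 15.6-fold. Smooth muscle and pericyte markers rose in 11 of 11, with a median of 1.87 (adjusted p = 9.55e-06; adjusted p = 0.107 with an estimated correlation). Of these, Des also stands in the sarcomere list and Acta2 in the fetal and stress list, and heart muscle cells can express Abcc9, so this list does not mark another cell type alone. The 4 erythroid genes rose with a median of 5.02, or 4.62 with bounds (adjusted p = 0.00734; adjusted p = 0.175 with an estimated correlation). Alpha globin Hba-a1 was higher by at least 962-fold; near-identical globin copies can share a probe. Epicardial markers rose in 6 of 7 and fell in 1, with a median of 2.7, or 2.19 with bounds (adjusted p = 0.0117; adjusted p = 0.26 with an estimated correlation). The epicardial call was lost in the deposited gene-level tables matched to 5949 genes (adjusted p = 0.156 normalized and 0.243 not normalized); with wider matching, to 8914 genes, it was lost only in the non-normalized one (adjusted p = 0.0733). The mast cell call was lost among genes detected on all 9 arrays (adjusted p = 0.198). Of the erythroid genes, Slc4a1 lost its call in the non-normalized gene-level table (adjusted p = 0.101). Hbb-b2 lost its call there (adjusted p = 0.105) and without background correction (0.0741).

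Smaller lists and regulatory lists differed as follows. Atrial genes rose in 7 of 9 (8 adjusted over the list alone) and fell in 1, with a median of 4.97, or 4.45 with bounds (adjusted p = 0.00098; adjusted p = 0.175 with an estimated correlation). Immediate early and heat shock genes rose in 16 of 19, with a median of 2.26, or 2.03 with bounds (adjusted p = 3.49e-05; adjusted p = 0.175 with an estimated correlation). Fosb was higher by at least 54.3-fold. Interferon genes rose in 9 of 13, with a median of 1.14, or 0.911 with bounds (adjusted p = 0.00835; adjusted p = 0.175 with an estimated correlation). They were not called among genes detected on all 9 arrays (adjusted p = 0.0551). The 2 adipocyte markers tested, Cidea and Pparg, rose, with a median of 3.73, or 3.31 with bounds (adjusted p = 0.0264; adjusted p = 0.175 with an estimated correlation); that list call was lost without eCSC replicate 2 (adjusted p = 0.0902, median 2.67), YFP-positive replicate 2 (0.0715, median 2.47) or adult replicate 3 (0.071, median 2.74), without background correction (0.0512, median 1.87) and with no filter on dim probes (0.0698, median 0.0867). The 3 skeletal muscle markers rose by a median of 1.04 and the list was not called (adjusted p = 0.124). Stem and progenitor genes rose in 8 of 12 and fell in 3, with a median of 1.46, and were not called as a list (camera adjusted p = 0.0579). The list was called with median scaling (adjusted p = 0.0291), with no normalization (0.0275) and with no filter on dim probes (0.0406, median 0.0989). It was also called with the mean of probes (0.0462) and without adult replicate 1 (0.049) or 2 (0.0454). Kit, the receptor by which eCSCs were isolated, was undetected on all eCSC arrays and at 8.24 ± 0.73 (SD, n = 3) in YFP-positive cardiomyocytes, at least 11.3-fold higher (adjusted p = 8.79e-09). Its raw signal was 182.3 on YFP-positive replicate 2, against 479.7 and 502.5 on replicates 1 and 3. These values are those of its brightest probe, and its other probes are described below.

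Genes highest in eCSCs included Adh7, at least 146-fold lower in YFP-positive cardiomyocytes (adjusted p = 3.19e-14), Cdsn, at least 126-fold, the growth factor Fgf7, at least 52.2-fold, and Steap1, at least 37.2-fold lower. Enzymes of serine and asparagine synthesis fell, with log2 differences of -5.98 ± 0.32 SE for Phgdh (adjusted p = 6.38e-10) and -5.78 ± 0.20 SE for Asns (adjusted p = 4.01e-12). Trib3 (-6.22 ± 0.27 SE), Bcat1 (-5.91 ± 0.22 SE) and Prkg2 (-5.74 ± 0.21 SE; detected on 2 of 3 YFP-positive arrays) fell too. In all, 7314 of 10024 genes were called, 3446 higher and 3868 lower. The groups of 7624 genes did not overlap over the arrays (76.1%), where chance gives 10%. At least 2-fold differences numbered 4585, but 2548 without background correction and 2492 in the series matrix, over the same genes. Without background correction 18 of the 19 lists called stayed so, while 13 medians moved by over 1.5 times, all toward 0: leukocyte markers to 1.35, mast cell to 1.07, epicardial to 1.15, endothelial to 3.32, fibroblast to 0.826, smooth muscle to 0.834, erythroid to 2.96, atrial to 2.83, glycolysis to 0.579, cardiac transcription factors to 1.51, interferon to 0.455 and immediate early genes to 1.37, besides the adipocyte list. Another scaling moved the split: 47.1% of calls were higher as reported, 34.8% with median scaling, 32.8% with no normalization and 60.6% with median scaling on probes detected on all 9 arrays, settings under which the median of all genes lay at -0.10, -0.49, -0.55 and 0.26. Requiring detection on all 9 arrays left 6536 genes and 4610 calls, and the deposited gene-level tables, matched to 5949 genes, gave 4320 calls (normalized) and 3881 calls (not normalized).

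Adult cardiomyocytes against eCSCs gave the reference for a mature heart muscle cell. Contractile and fatty acid genes led: Fabp3 was at least 1020-fold, Actc1 at least 994-fold, Lpl at least 987-fold, Myh6 at least 984-fold and Myl3 at least 981-fold higher (adjusted p = 1.46e-15 for Fabp3). Of 22 sarcomere genes 21 rose and 1 fell, with a median of 8.35, or 8.14 with bounds (camera adjusted p = 3.62e-12, and adjusted p = 0.0446 with an estimated correlation). The gene that fell was Tpm1 (-3.91, named after its values were seen), with the limit on its probes given above. All 20 calcium handling genes rose, with a median of 3.71, or 3.48 with bounds (adjusted p = 1.11e-10; adjusted p = 0.0446 with an estimated correlation). Ryr2 was higher by at least 152-fold. All 26 fatty acid and energy transfer genes rose, with a median of 4.29, or 4.12 with bounds (adjusted p = 1.13e-12; adjusted p = 0.102 with an estimated correlation), and 31 of 33 oxidative phosphorylation genes rose and 1 fell, with a median of 2.16 (adjusted p = 1.98e-10; adjusted p = 0.138 with an estimated correlation). Glycolysis genes rose in 11 of 16 and fell in 3, with a median of 1.17 (adjusted p = 0.0119; adjusted p = 0.302 with an estimated correlation). They were not called among genes detected on all 9 arrays (adjusted p = 0.0603). Of 14 cardiac transcription factors 13 rose and 1 fell, with a median of 2.38 (adjusted p = 1.94e-05; adjusted p = 0.0446 with an estimated correlation). Gata4 was higher by at least 3.16-fold and Nkx2-5 by 3.98 ± 0.17 SE. The fetal and stress list rose in 10 of 11, with a median of 2.94, or 2.49 with bounds (adjusted p = 0.000167; adjusted p = 0.0446 with an estimated correlation). Nppa was higher by at least 134-fold.

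Proliferation genes were far lower in adult cardiomyocytes than in eCSCs. All 32 cell cycle genes fell, with a median of -3.87, or -3.57 with bounds (adjusted p = 2.75e-12; adjusted p = 0.102 with an estimated correlation), among them Prc1 (-6.00 ± 0.21 SE; detected on 2 of 3 adult arrays) and Cdc20 (-5.71 ± 0.19 SE; on 1). Anln was at least 68.6-fold lower. Other large falls were those of Lgals3 (-7.81 ± 0.27 SE), Asns (-7.47 ± 0.20 SE), Trib3 (-7.31 ± 0.27 SE), Psat1 (-7.14 ± 0.23 SE) and Plac8 (-6.87 ± 0.34 SE). Trib3 was detected on 2 of 3 adult arrays, and Psat1 and Plac8 on 1. Fibroblast markers fell in 15 of 24 and rose in 7, with a median of -1.09, or -0.90 with bounds, and were not called as a list (adjusted p = 0.0638), though they were with no filter (adjusted p = 0.0144), among genes detected on all 9 arrays (0.0172), with the mean of probes (0.0485), with scaling on probes detected on all 9 arrays (0.0443) and without adult replicate 2 (0.0451). Col1a1 fell by 3.17 ± 0.27 SE (adjusted p = 6.2e-08). Endothelial markers rose in 15 of 17 and fell in 1, with a median of 3.02, or 2.79 with bounds (adjusted p = 3.42e-05; adjusted p = 0.21 with an estimated correlation). They were not called among genes detected on all 9 arrays (adjusted p = 0.256). Leukocyte markers rose in 12 of 18 and fell in 1, with a median of 1.23, or 0.962 with bounds (adjusted p = 0.00262; adjusted p = 0.393 with an estimated correlation). They were not called in the gene-level tables matched to 5949 genes (adjusted p = 0.108 normalized and 0.354 not normalized); with wider matching the call was lost only in the non-normalized one (adjusted p = 0.155). Smooth muscle markers rose in 10 of 11, with a median of 2.28 (adjusted p = 0.000157; adjusted p = 0.139 with an estimated correlation). Of 4 erythroid genes 1, Hba-a1, rose by at least 43.9-fold, with a list median of 0.152 (adjusted p = 0.536), and Kit was undetected in both groups (adjusted p = 0.119). Kit was called higher in adult cells without YFP-positive replicate 2 (adjusted p = 0.00774), on the 6 arrays alone (0.012), with array weights (0.0267) and with scaling on probes detected on all 9 arrays (9.31e-05). These calls compare undetected signals, with means of 4.212 in eCSCs and 4.7 in adult cells, so they do not show that Kit differed.

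Mast cell markers rose in 0 of 8 and 1, Gata2, fell (adjusted p = 0.876): the median was 0.06, the mean -0.19 and the test pointed down. Epicardial markers rose in 1 of 7 (0 adjusted over the list alone) and fell in 1, with a median of 0.04, a mean of -0.53 and a test pointing down (adjusted p = 0.876). Stem and progenitor genes rose in 6 of 12 and fell in 4, with a median of 0.50, a mean of -0.20 and a test pointing up (adjusted p = 0.901). Interferon genes rose in 3 of 13 and fell in 4, with a median of 0.21, or 0.0612 with bounds, a mean of -0.0092 and a test pointing up (adjusted p = 0.876). Immediate early genes rose in 3 of 19 and fell in 5 with a median of -0.0925 (adjusted p = 0.876), and skeletal muscle markers rose in 2 of 3, with a median of 1.43, or 1.01 with bounds (adjusted p = 0.164). Atrial genes rose in 6 of 9 and fell in 1, with a median of 1.32, or 0.872 with bounds (adjusted p = 0.125). They were called with median scaling (adjusted p = 0.0325), with no normalization (adjusted p = 0.03) and in the normalized gene-level table with wider matching (adjusted p = 0.0435). The 2 adipocyte markers rose, with a median of 4.38, or 3.96 with bounds (adjusted p = 0.049; adjusted p = 0.284 with an estimated correlation), a list call that ended without eCSC replicate 2 (adjusted p = 0.088, median 2.72), eCSC replicate 3 (0.0584), YFP-positive replicate 2 (0.0674, median 2.78), YFP-positive replicate 3 (0.0509) or adult replicate 3 (0.0649, median 2.47), without background correction (0.0795, median 2.46), with no filter (0.134, median 0.106) or a stricter filter on dim probes (0.0553), in the series matrix (0.0603, median 2.52) and with scaling on probes detected on all 9 arrays (0.0646). Without background correction 11 of the 12 lists called stayed so, and 6 medians moved by over 1.5 times toward 0: calcium handling to 2.3, glycolysis to 0.743, endothelial to 1.53, leukocyte to 0.412 and smooth muscle to 0.91, besides the adipocyte list; in the series matrix the cell cycle median also did, to -2.54. In all, 7540 of 10024 genes were called, 3590 higher and 3950 lower; 77.7% of genes had groups that did not overlap, where chance gives 10%. Calls were higher in 47.6% as reported, 29.3% with median scaling, 26% with no normalization and 61.9% with scaling on probes detected on all 9 arrays, where the median of all genes lay at -0.049, -0.68, -0.81 and 0.39. Requiring detection on all 9 arrays gave 4935 calls, and the deposited gene-level values gave 4443 calls (normalized) and 4107 calls (not normalized).

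**Figure D1:**
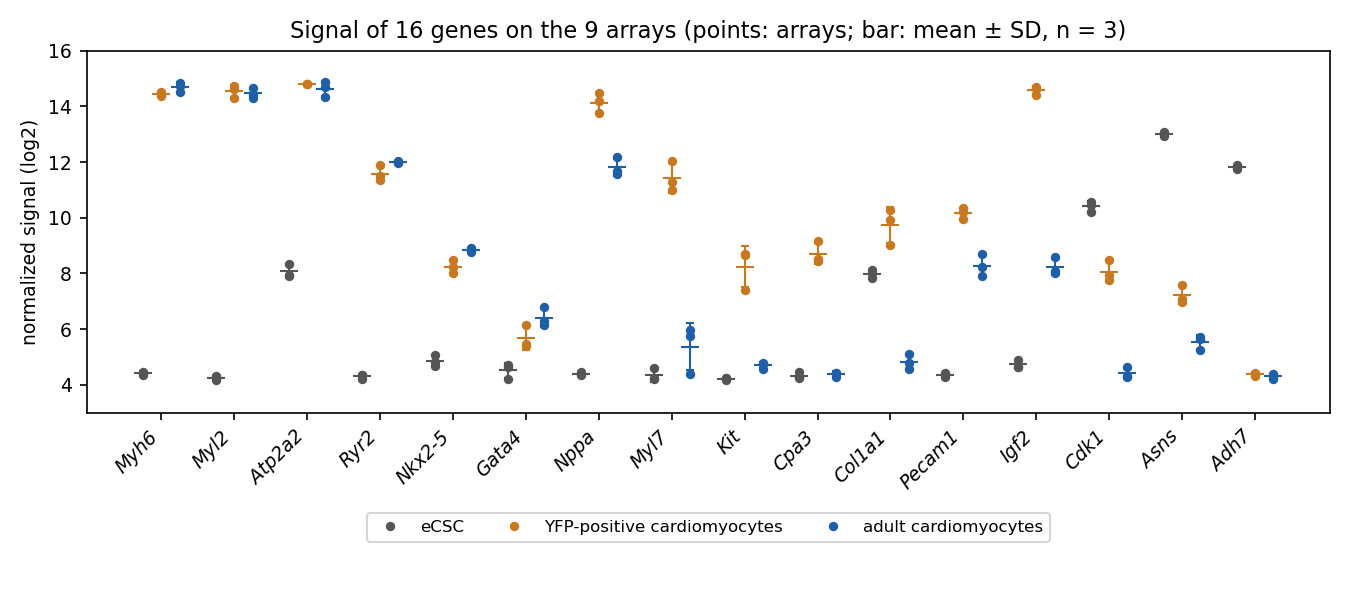
Normalized log2 signal (vertical axis) of 16 genes on each of the 9 arrays; points are arrays, and bars give the mean ± SD of 3 arrays per group. Myh6 stood at 14.46 in YFP-positive and 14.69 in adult cardiomyocytes and was undetected in eCSCs (4.42), whereas Kit and Cpa3 were detected in YFP-positive cardiomyocytes only; the genes drawn were chosen after their values were seen.

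The comparison of YFP-positive with adult cardiomyocytes asked how closely the labelled cells matched mature muscle. No difference was called for several contractile and calcium genes: Myh6 differed by -0.23 ± 0.16 SE (adjusted p = 0.248), Myl2, named after its values were seen, by 0.08 ± 0.17 SE (adjusted p = 0.717), and Actc1 by -0.32 ± 0.15 SE (adjusted p = 0.101). Ryr2 differed by -0.41 ± 0.18 SE (adjusted p = 0.0658), Myh7 by -0.02 ± 0.30 SE (adjusted p = 0.966) and Atp2a2 by 0.16 ± 0.19 SE (adjusted p = 0.494). Ryr2 and Actc1 were called lower under some settings, such as array weights (adjusted p = 0.0103 and 0.0431), Ryr2 also without YFP-positive replicate 2 (0.0114), as was Myh6 with the mean of its probes (adjusted p = 0.00106). Myh6 (14.46 and 14.69), Actc1 (14.38 and 14.70), Myl2 (14.55 and 14.47) and Atp2a2 (14.81 and 14.64) stood near the top of the arrays' range in both groups, where a difference can be compressed, so their closeness does not show equal levels. Atp2a2 was lower by 0.22 with scaling on probes detected on all 9 arrays, and Myh7 was higher under all 3 other scalings. Atrial and fetal forms were higher in YFP-positive cardiomyocytes: the atrial light chain Myl7 by 6.06 ± 0.35 SE (adjusted p = 1.4e-08), sarcolipin Sln by 5.76 ± 0.36 SE, Myl4 by 4.76 ± 0.29 SE, slow troponin Tnni1 by at least 18-fold and Nppa by 2.34 ± 0.21 SE (adjusted p = 1.03e-06). Myl7 and Sln were detected on 2 of 3 adult arrays, so that their sizes are uncertain. Atrial genes rose in 8 of 9 and fell in 1, with a median of 2.34 (adjusted p = 5.73e-05; adjusted p = 0.138 with an estimated correlation). The fetal and stress list rose in 5 of 11 and fell in 3, with a median of 0.29 (adjusted p = 0.0458; adjusted p = 0.152 with an estimated correlation); the call ended under median scaling (adjusted p = 0.167), with no normalization (0.13), and without eCSC replicate 3 (0.0542), YFP-positive replicate 1 (0.0541) or replicate 2 (0.0718), among genes detected on all 9 arrays (0.185) and with a stricter filter on dim probes (0.0507).

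Genes of energy supply and electrical function were modestly lower in YFP-positive cardiomyocytes. Oxidative phosphorylation genes fell in 27 of 33 cases (28 adjusted over the list alone), with a median of -0.79 (adjusted p = 1.27e-06; adjusted p = 0.153 with an estimated correlation), and fatty acid and energy transfer genes in 22 of 26, with a median of -0.95 (adjusted p = 1.04e-06; adjusted p = 0.153 with an estimated correlation). Mitochondrial creatine kinase Ckmt2 (-1.15 ± 0.18 SE), Acadm (-1.17 ± 0.18 SE) and Ndufa5 (-1.11 ± 0.17 SE) fell. Both lists stayed lower under every scaling, with medians of -0.675 to -1.07 and -0.772 to -1.16. Calcium handling and channel genes fell in 13 of 20, with a median of -0.79 (adjusted p = 0.000138; adjusted p = 0.133 with an estimated correlation), among them the potassium channel Kcnj2 (-1.72 ± 0.17 SE, adjusted p = 3.25e-06; detected on 2 of 3 YFP-positive arrays). Sarcomere genes fell in 14 of 22 and rose in 2, Myl7 and Tpm1, with a median of -0.525 (adjusted p = 0.0162; adjusted p = 0.277 with an estimated correlation). Among genes detected on all 9 arrays neither the sarcomere (camera adjusted p = 0.72, median -0.531) nor the calcium list (0.912, median -0.164) was called. Glycolysis genes fell in 6 of 16 and rose in 1, with a median of -0.45, and were not called (adjusted p = 0.0688), though they were under several other settings, such as median scaling (adjusted p = 0.00543), no normalization (0.00542) and leaving out adult replicate 2 (0.0406).

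Cardiac transcription factors fell in 6 of 14 and rose in 2, with a median of -0.32, and were not called as a list (adjusted p = 0.397). Smyd1 (-1.02 ± 0.19 SE, adjusted p = 0.000632), Irx4 (-0.73 ± 0.17 SE), Tbx5 (-0.71 ± 0.16 SE), Gata4 (-0.73 ± 0.24 SE) and Nkx2-5 (-0.59 ± 0.17 SE) fell. All 5 calls were lost with median scaling (adjusted p = 0.222, 0.331, 0.558, 0.49 and 0.295 in that order) and with no normalization (adjusted p = 0.381, 0.527, 0.768, 0.702 and 0.504). Nkx2-5 was also lost without YFP-positive replicate 1 (adjusted p = 0.0558), and Gata4 without YFP-positive replicate 1 (0.074) or 3 (0.0879) or adult replicate 3 (0.0946), without background correction (0.0572), with no filter (0.0632), with scaling on probes detected on all 9 arrays (0.0817) and in the non-normalized gene-level table (0.0834). Tnni3 fell by 0.54 ± 0.18 SE (adjusted p = 0.0228), a call lost with no normalization (0.124) and without YFP-positive replicate 1 (0.094) or 3 (0.0663) or adult replicate 2 (0.103) or 3 (0.0714). The largest falls were those of Fgf16 (-2.71 ± 0.21 SE, adjusted p = 1.89e-07), Dynll2 (-2.61 ± 0.37 SE), Acsl6 (-2.54 ± 0.31 SE), Asb14 (-2.35 ± 0.24 SE), the Z-disc protein Myot (-2.32 ± 0.26 SE) and the sodium channel subunit Scn4b (-2.30 ± 0.27 SE); Fgf16 and Myot were detected on 2 of 3 YFP-positive arrays.

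Markers of other cell types were higher in YFP-positive than in adult cardiomyocytes. Fibroblast and matrix markers rose in 22 of 24, with a median of 2.84, or 2.79 with bounds (adjusted p = 1.89e-17; adjusted p = 0.105 with an estimated correlation). Col1a1 was higher by 4.92 ± 0.27 SE (adjusted p = 9.2e-09; detected on 1 of 3 adult arrays) and Vim by 4.45 ± 0.25 SE. Endothelial markers rose in 15 of 17 and fell in 1, with a median of 1.71 (adjusted p = 3.96e-08; adjusted p = 0.105 with an estimated correlation). Pecam1 was higher by 1.88 ± 0.20 SE (adjusted p = 5.42e-06). Leukocyte markers rose in 11 of 18 (12 adjusted over the list alone), with a median of 0.89 (adjusted p = 7.33e-05; adjusted p = 0.21 with an estimated correlation). All 8 mast cell markers rose, with a median of 2.49, or 2.06 with bounds (adjusted p = 6.05e-08; adjusted p = 0.105 with an estimated correlation). The protease Cpa3 was higher by at least 14.4-fold and Cma1, detected on 1 of 3 adult arrays, by 3.85 ± 0.21 SE. All 4 erythroid genes rose, with a median of 4.24, or 3.99 with bounds (adjusted p = 0.000258; adjusted p = 0.105 with an estimated correlation). Hba-a1 was higher by 4.46 ± 0.23 SE, a size that can be understated, since its level of 14.66 in YFP-positive cells stood near the top of the arrays' range. Slc4a1 lost its call in the non-normalized gene-level table (1.369, adjusted p = 0.138, against a reported 4.033). All 7 epicardial markers rose, with a median of 2.64, or 2.07 with bounds (adjusted p = 5.54e-06; adjusted p = 0.133 with an estimated correlation). Upk3b was higher by 4.59 ± 0.38 SE but was detected on only 1 of 3 adult arrays. Smooth muscle and pericyte markers rose in 3 of 11 and fell in 3, with a median of 0.14 (adjusted p = 0.797). The adipocyte list (1 of 2 fell, adjusted p = 0.309) and the skeletal muscle list (1 of 3 fell, adjusted p = 0.699) were not called; the skeletal median was 0.10, its mean -0.24, and its test pointed down. Without YFP-positive replicate 2, the YFP-positive array closest to the adult ones, the medians were 3.02 for fibroblast, 1.69 for endothelial, 1.04 for leukocyte, 2.51 for mast cell, 4.42 for erythroid and 3.06 for epicardial markers, and all 6 lists were still called.

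Genes of proliferation and early response were higher in YFP-positive than in adult cardiomyocytes, as were the single genes with the largest rises. Elastin, Eln, was higher by 6.47 ± 0.25 SE (adjusted p = 4.88e-10), the growth factor Igf2, at 14.58 also near the top of the range, by 6.35 ± 0.19 SE (adjusted p = 7.39e-11), Cxcl1 by 6.04 ± 0.32 SE and Ptn by 5.82 ± 0.20 SE, while Dlk1 was at least 56.8-fold and Stfa1 at least 52.2-fold higher. Eln was detected on 2 of 3 adult arrays, Cxcl1 and Ptn on 1. Cell cycle genes rose in 27 of 32, with a median of 1.76, or 1.69 with bounds (adjusted p = 9.65e-14; adjusted p = 0.105 with an estimated correlation). Prc1, detected on 2 of 3 adult arrays, was higher by 3.82 ± 0.21 SE and Mcm5 by 3.38 ± 0.20 SE. Immediate early and heat shock genes rose in 17 of 19 and fell in 1, with a median of 2.52 (adjusted p = 1.18e-09; adjusted p = 0.105 with an estimated correlation). Fos, detected on 2 of 3 adult arrays, was higher by 6.08 ± 0.42 SE and Fosb by at least 50.1-fold. Interferon genes rose in 9 of 13 (10 adjusted over the list alone), with a median of 0.911, or 0.872 with bounds (adjusted p = 5.73e-05; adjusted p = 0.105 with an estimated correlation). Stem and progenitor genes rose in 8 of 12 and fell in 1, with a median of 1.39, or 1.3 with bounds (adjusted p = 0.00126; adjusted p = 0.105 with an estimated correlation). Kit was undetected on all adult arrays and at least 10.4-fold higher in YFP-positive cardiomyocytes (adjusted p = 2.2e-07), and Klf4 was higher by 3.33 ± 0.30 SE.

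**Figure D2:**
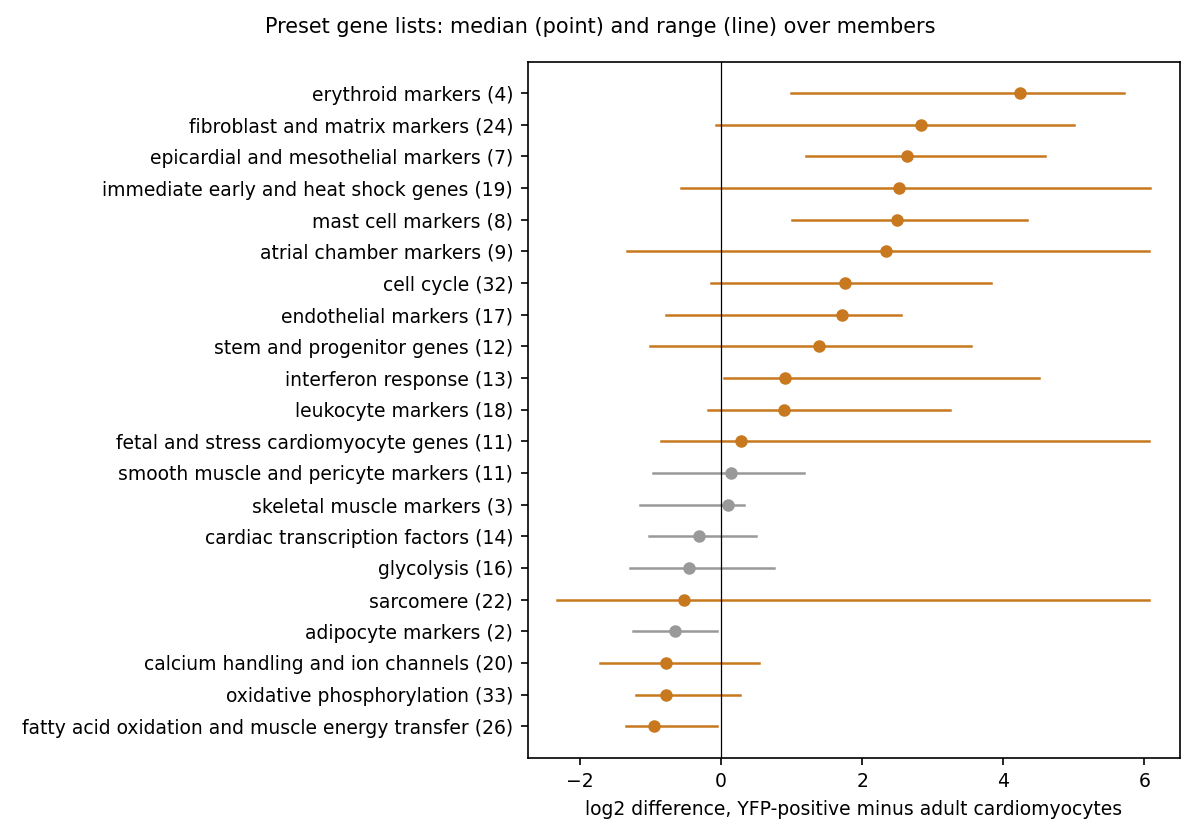
Log2 difference of YFP-positive minus adult cardiomyocytes (horizontal axis) for the 21 preset gene lists, with the number of members tested in brackets; points are medians, lines run from the lowest to the highest member, and coloured lists were called by camera at its preset correlation. The erythroid median was 4.24 and the fibroblast median 2.84, whereas the oxidative phosphorylation median was -0.79; 0 lists were called with an estimated correlation.

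In all, 5063 of 10024 genes were called between YFP-positive and adult cardiomyocytes, 2284 higher and 2779 lower, and 1957 differed at least 2-fold, 1251 higher and 706 lower. That 2-fold count was 811 without background correction and 731 in the series matrix, over the same genes, and 423 (normalized) and 505 (not normalized) of 5949 genes in the gene-level data. All 16 lists called stayed so without background correction, but 7 medians moved by over 1.5 times toward 0: cell cycle to 0.802, mast cell to 1.22, epicardial to 1.1, leukocyte to 0.427, stem and progenitor to 0.706, interferon to 0.468 and immediate early genes to 1.65. In the non-normalized gene-level table the cell cycle median was 0.172. The groups did not overlap for 58.7% of genes, where chance gives 10%. The count was 5368 without YFP-positive replicate 2. It was 3082 with median scaling and 2685 with no normalization; calls were higher in 45.1% as reported and in 73.2%, 82.2% and, with scaling on probes detected on all 9 arrays, 43.8% under the others, where the median of all genes lay at -0.08, 0.16, 0.24 and -0.16. Requiring detection on all 9 arrays gave 3365 calls, and the deposited gene-level values gave 3074 calls (normalized) and 2453 calls (not normalized).

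The 3 groups were then compared together. On a line from the eCSC mean (0) to the adult mean (1) over all genes tested, YFP-positive cardiomyocytes lay at 0.782 ± 0.050 (SD, n = 3), with arrays at 0.753, 0.839 and 0.753, and at 0.754 without replicate 2. They lay 0.448 ± 0.047 (SD, n = 3) of that distance off the line, against 0.161 for eCSC and 0.167 for adult arrays projected on lines made without them. The sarcomere list lay at 0.938 ± 0.016, cardiac transcription factors at 0.929 ± 0.024 and oxidative phosphorylation at 0.826 ± 0.042. Cell cycle genes lay at 0.491 ± 0.057, and atrial genes past the adult mean at 1.51 ± 0.054. Genes with the largest eCSC to adult differences weigh most, and several such sarcomere genes stood near the top of the arrays' range. The sarcomere position can therefore lie too close to 1, and 14 of 22 sarcomere genes were called lower than in adult cells. Over genes detected on all 9 arrays the position was 0.715. Of 6109 genes called in both kinds of cardiomyocyte against eCSCs, 5956 changed in the same direction, 2715 higher and 3241 lower. Independent lists would share 1234 and 1524, and 100 simulations of unchanged groups against the same eCSC arrays gave a mean of 0.010 shared genes and at most 1. The fold changes correlated across genes at r = 0.875, against 0.501 in the simulations, with a covariance of 2.98 against 0.022 (a difference of 2.95); the eCSC arrays could not be split into parts of 2 each, so part of the excess of the shared count over independent lists may come from the shared eCSC arrays. The shared count was 3633 at 2-fold or more, 3775 with detection on all 9 arrays, and 3506 (normalized) and 3091 (not normalized) in the gene-level data.

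The moderated F test called 8677 of 10024 genes as differing among the groups (5618 with detection on all 9 arrays; 5087 and 4694 in the normalized and non-normalized gene-level data). The most frequent pattern, 2118 genes, was a lower level than in eCSCs in both kinds of cardiomyocyte with no difference called between these. A further 1294 genes were above eCSCs in both and lower in YFP-positive than in adult cells, and 1050 were above in both with no difference called. YFP-positive cardiomyocytes were above both other groups for 974 genes and below both for 685. The largest such rises were those of Eln, Igf2, Stfa1, Dlk1 and Fos, and the largest falls those of Nqo1 (-2.88 against eCSCs and -2.28 against adult cells on the log2 scale), Psmb1, Gchfr, Plpbp and Bdnf.

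**Figure D3:**
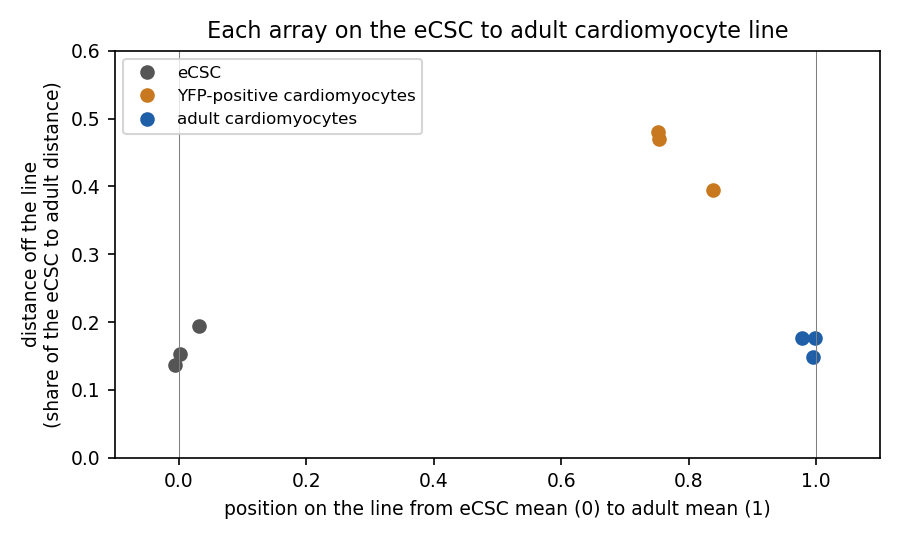
Each array's position on the line from the eCSC mean (0) to the adult cardiomyocyte mean (1) on the horizontal axis, and its distance off that line, as a share of the eCSC to adult distance, on the vertical axis. The 3 YFP-positive arrays lie at 0.753, 0.753 and 0.839 and farther off the line (0.395 to 0.48) than the other 6 (0.137 to 0.194).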

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

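Of the tests below, only the one on normalization between arrays and the counts over other splits of the samples were set before their results were seen; the others were chosen afterwards.

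In 119 genes the level was above that of eCSCs in YFP-positive cardiomyocytes and below it in adult cardiomyocytes, and in 34 genes the reverse held. All 153 were also called between YFP-positive and adult cardiomyocytes. Their choice by opposite calls against the same eCSC arrays made that nearly certain, so it is no independent support. The 119 include 8 of 24 fibroblast and matrix markers (Col1a1, Col1a2, Col3a1, Col5a1, Col6a1, Lox, Loxl1 and Sparc), named after their values were seen. They also include Klf4, Cav1, Isg15, Oasl2, Junb, Jund and Atf3, likewise named after their values were seen.

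A signal was also present in probes that the comparisons do not use. Without a gene name in the annotation used here, 2536 probes were detected on all 3 arrays of a group. Of these, 1741 were called between YFP-positive cells and eCSCs, 1857 between adult cells and eCSCs and 1130 between YFP-positive and adult cells.

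Markers of fibroblasts, endothelium, leukocytes, mast cells, erythroid cells and epicardium were higher in YFP-positive than in adult cardiomyocytes. The normalization between arrays is argued against: all 6 lists kept a median above 0.5 with no normalization (1.2 to 4.39) and with scaling on probes detected on all 9 arrays (0.811 to 4). One lower share of cardiomyocyte RNA that raised every other cell type alike would shift fibroblast and endothelial markers equally. That holds only if cardiomyocytes express none of these markers, which was not tested. Here 13 fibroblast members rose by a mean of 3.11 and 15 endothelial members by 1.62. The gap was 1.48 (permutation p = 2e-05, two-sided, over genes, which are not independent). It argues against a single equal rise under that condition only. A lower share together with another mix of the other cell types could give such a gap, was not tested and stays open. The sarcomere, calcium handling, fatty acid and oxidative phosphorylation lists had medians of -0.525, -0.785, -0.952 and -0.788, a direction that a lower share could also give. The fetal and stress list and the atrial list were higher. Cells of other types among the sorted cells stay open as a hypothesis. In 6 of 6 lists at least 50% of members were detected on all 3 YFP-positive arrays and higher than in adult cells. Hba-a1 stood at 14.66 and Col1a1 at 9.75. Sorting for YFP may remove unlabelled cells. Since Cre was under c-kit control, it need not remove cells of another type that were labelled through their own c-kit expression. Members also detected on all adult arrays numbered 15 of 24 for fibroblasts, 17 of 17 for endothelium, 13 of 18 for leukocytes, 2 of 8 for mast cells, 1 of 4 for erythroid cells and 0 of 7 for epicardium, and 2 fibroblast and 1 endothelial member stand in another list; gene expression by the labelled cells themselves was not tested and cannot be told apart from such cells here.

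Kit was detected on all 3 YFP-positive arrays and on 0 eCSC and 0 adult arrays. Because a Kit probe was detected on 0 of 3 eCSC arrays, this signal did not stand at the level of the cultured eCSCs. That restates the pattern and is no separate test, and it does not bear on the Kit level of such cells before culture. Mast cells among the sorted cells are a candidate source: 7 of 7 mast cell markers other than Gata2 were detected on all 3 YFP-positive arrays and higher than in adult cells, with Cpa3 at 8.71, and 2 of all 8 markers were detected on all adult arrays, but nothing here separates their Kit from that of other cells. A single Kit probe reading another transcript also stays open. Of the other Kit probes, 1 was higher on every YFP-positive array than on every other array but was detected on only 2 of 3. Its lowest YFP-positive signal was 4.585 and its highest elsewhere 4.455 after normalization, both near background. The remaining Kit probe was detected on 0 arrays of each group, so the Kit result rests mainly on 1 probe.

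Myl7, Sln, Myl4, Tnni1 and Nppa, cardiac genes of the fetal or atrial program, were higher in YFP-positive than in adult cardiomyocytes. The hypertrophic stress response to isoproterenol stays open: 0 of 4 of its genes (Nppb, Acta1, Myh7 and Ankrd1) were called higher, and Acta1 fell by 0.78 and Ankrd1 by 0.48 on the log2 scale, but Nppa, also a gene of this response, is outside these 4 and was higher. The labels do not settle whether the adult cells came from treated mice; Acta1 and Ankrd1 were named after their values were seen. Atrial muscle in the sorted sample also stays open, although the stated dissection of the left ventricular apex would leave out atria: 1 of 2 ventricular genes, Irx4, was lower, a call lost under median scaling, and Myl2, near the top of the arrays' range, was not called. An immature state of the labelled cells may account for the pattern and was not tested.

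Chance assignment of the arrays was counted over other splits of the samples. Between 2 groups there are 10 splits of 6 arrays, too few for a share under 0.05, and 1 of 10 reached the real count in each comparison. The real counts from the 6 arrays alone were 7277, 7581 and 4945 genes, and the highest other split gave 0 in each. Over the 3 groups 1 of 100 splits drawn from 280, the real one, gave as many as 8677 genes and the highest other gave 5570. This argues against a chance assignment of these arrays to the groups. The labels do not say whether samples came from separate animals or cultures, so chance differences between animals or cultures are not covered.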

How the results depend on the processing

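Scaling on probes detected on all 9 arrays and the wider name matching were chosen after the data were seen; the other alternatives were set before. With an estimated correlation 7 lists were called in place of 47. By fry 56 were called: 9 gained a call and 0 lost one. Those that gained one include the stem and progenitor list between YFP-positive cells and eCSCs (fry adjusted p = 0.000113). The fibroblast list between adult cells and eCSCs (0.000218) and cardiac transcription factors between YFP-positive and adult cells (0.0019) gained one too. YFP-positive against adult cells gave 3082 genes with median scaling and 2685 with no normalization. In the normalized gene-level table the counts were 4320, 4443 and 3074 for the comparisons in the order reported, 5087 by the F test and 3506 shared; in the non-normalized one they were 3881, 4107, 2453, 4694 and 3091. Fewer genes were tested there (5949 of 10024); wider matching, to 8914 genes, gave 6474, 6658, 4545, 7629 and 5247, and 5790, 6186, 3581, 7017 and 4633. Detection on all 9 arrays (6536 genes tested) gave 4610, 4935, 3365, 5618 and 3775, a position of 0.715 and 31 lists. At least 2-fold were 4585 and 1957 genes, with 3633 shared. The position was 0.938 on the sarcomere list alone, and the Spearman correlation with adult arrays, a different quantity, was 0.871. Except for fewer genes tested, the cause was not tested. Between adult cells and eCSCs, 2 genes reversed with scaling on probes detected on all 9 arrays. Hbb-b2 turned to 0.81 (adjusted p = 0.00996, against a reported -0.22, adjusted p = 0.381). Krt8 turned to 0.86 (adjusted p = 0.0289, against a reported -0.099, adjusted p = 0.82). This setting also moved other genes upward, such as Mcpt4 from 0.160 to 1.248 and Cma1 from 0.109 to 1.062. The median of all genes moved from -0.049 to 0.39. The 2 reversals are therefore part of a shift common to many genes and do not show changes particular to Hbb-b2 and Krt8.

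Leaving out each array in turn gave 6892 to 7359, 7190 to 7652 and 4165 to 5368 genes, 8391 to 8840 by the F test, positions of 0.754 to 0.796, 5556 to 5856 shared genes and 44 to 50 lists. The replicate numbers did not pair the samples: deviations of same-numbered samples correlated at -0.064 to 0.12, above 0.1 in 1 of 9 pairs. The fit with the replicate block gave 7307, 7528 and 5040 genes, 8640 by the F test, 5950 shared and 48 lists; among lists and named genes it changed only the call of the list of stem and progenitor genes between YFP-positive cells and eCSCs (adjusted p = 0.0496). Of 4725 values of named genes under other settings 4649 stayed on their side of the threshold, 50 lost their call, 24 gained one and 2 reversed. Of 981 list values 887 stayed, 64 lost their call and 30 gained one. With arrays left out, 2704 of 2727 gene values and 552 of 567 list values stayed. A value that turned sign with no call under either setting counts here as having stayed. A block for slide or chip was not run. Between YFP-positive and adult cells, Pparg, Pvalb, Myh7 and Atp2a2, none of them called, turned sign under some scalings. Signals near background limit what can be said of dim genes, for which only bounds are given.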

Other observations

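The lists and genes in this part were chosen after the results were seen, with Igf2 and Dlk1 of the imprinted list already known to be among the largest rises. The camera p-values of these lists, adjusted over the 4 lists of a comparison, were therefore computed on genes picked with their values in view and are no independent evidence that a list shifted. The 4 genes of the hypertrophic stress list also served the test of the isoproterenol response.

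Of 11 tested genes of the imprinted growth network list, a set active in fetal tissue whose members need not all be imprinted, most were called higher in YFP-positive cardiomyocytes than in each other group. Against adult cardiomyocytes 9 of 11 rose (9 adjusted over the list alone), with a median of 3.02 (camera adjusted p = 2.15e-09; adjusted p = 0.036 with an estimated correlation): Gpc3 by 4.49 ± 0.24 SE, Peg3 by 3.45 ± 0.22 SE and Cdkn1c by 2.42 ± 0.19 SE on the log2 scale (limma adjusted p = 2.44e-07 for Cdkn1c). Mest, undetected in adult cells, was at least 20.9-fold higher. Against eCSCs 10 of 11 rose, with a median of 4.96 (camera adjusted p = 2.78e-06; adjusted p = 0.0512 with an estimated correlation). Between adult cells and eCSCs 6 of 11 rose and 2 fell, with a median of 0.992 (camera adjusted p = 0.060; adjusted p = 0.356 with an estimated correlation). Genes of neutrophil granules and the acute phase rose in 9 of 9 against adult cells, with a median of 2.89 (camera adjusted p = 2.38e-07; adjusted p = 0.118 with an estimated correlation): S100a8 by 5.37 ± 0.30 SE and S100a9, undetected in adult cells, by at least 13.8-fold. Against eCSCs 8 of 9 rose, with a median of 2.91 (camera adjusted p = 0.000516; adjusted p = 0.171 with an estimated correlation). Between adult cells and eCSCs S100a8 rose and Lcn2 fell, with a median of 0.113, a mean of -0.0739 and adjusted p = 0.906.

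Genes of the amino acid response, which supply and sense amino acids, were highest in eCSCs. They fell in 18 of 19 against eCSCs in YFP-positive cells, with a median of -4.12 (camera adjusted p = 6.72e-08; adjusted p = 0.0512 with an estimated correlation). In adult cells 18 of 19 fell as well, with a median of -4.96 (camera adjusted p = 6.88e-08; adjusted p = 0.0656 with an estimated correlation); Vldlr rose in both. Atf4, a transcription factor of this response, stood at 12.42 in eCSCs, 11.16 in YFP-positive and 9.01 in adult cells. YFP-positive cells were above adult cells in 8 of 19 and below in 2, with a median of 0.689 (camera adjusted p = 0.00155; adjusted p = 0.167 with an estimated correlation). The hypertrophic stress list fell in 2 of 4 between YFP-positive and adult cells, with a median of -0.482 (camera adjusted p = 0.241); it rose in 3 of 4 and 4 of 4 against eCSCs, with medians of 3.89 and 4.14 (camera adjusted p = 0.00967 and 0.013; adjusted p = 0.0523 and 0.0656 with an estimated correlation).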
